A study of Zea mays with 18 samples.

How the data were processed

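Poly-A RNA from maize (Zea mays) stems was sequenced in 18 libraries of paired-end reads, per the labels' protocols. The labels give 3 hybrids that share the parent Dan 598 and differ in plant height: low (Dan 598 x FAPW), middle (Dan 598 x CML444) and high (Dan 598 x ES40). Each hybrid was sampled at 3 stages, jointing (the start of stem elongation), big flare (the late whorl stage) and tasseling (tassel emergence), which makes 9 groups with 2 libraries each. The labels do not say whether the 2 libraries of a group came from separate plants, so p-values measure the spread between these libraries, which may be technical. Each height class is a single hybrid, so plant height and genotype are the same contrast here.

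The authors deposited FPKM values (fragments scaled by transcript length and by the mapped fragments of the library) for 34474 genes in the 18 libraries. The tools named, per the submitters' processing notes, are TopHat2, Cufflinks 2.2.1, Cuffdiff and DESeq 1.28.0, with the genome build B73 RefGen_v4. The notes give no role or order for them, and filters on reads or genes are not given in the sources used here. Of the identifiers, 32647 start with Zm00001d, 1673 with BGI_novel and 154 with GRMZM. FPKM divides by library size, so a few abundant genes can shift all others. The 10 most abundant genes held 5.38% to 10.21% of the FPKM sum.

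FPKM values keep no read counts, and the absolute depth is unknown. Relative depth was estimated from the ratios between libraries of the low FPKM values of 2454 genes, where steps of whole fragments show. For 81.7% of the 306 ordered pairs of libraries, the most frequent ratio lay within 0.05 log2 units of the fitted depths. On this scale the depth ran from 0.426 (high big flare, replicate 1) to 1.0 (low tasseling, replicate 2). Tasseling libraries were deeper (mean relative depth 0.863) than those of jointing (0.592) and big flare (0.54). Low values are less precise in the shallower libraries.

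Gene names are the best protein matches given in the deposited table, where 34351 genes had a match and 16209 an informative name. Symbols came from a reference table of assembly Zm-B73-REFERENCE-NAM-5.0 through the matched protein accession, found for 17823 genes. That assembly is not the authors' build, so it gave names only, and no coordinates are printed. None of the names was checked by sequence. Reads of near-identical copies can be split between genes, and values of multigene families such as small heat shock proteins and histones are uncertain in this respect.

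Tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) for the 26792 genes with an FPKM of 1 or more in at least 2 libraries. The other 7682 genes were not tested. The model had the 9 group means, 9 residual degrees of freedom and moderated variances with a mean trend, and all 18 libraries shared the estimate of the spread. Hybrids were compared as means of the 3 stages and stages as means of the 3 hybrids (6 libraries a side), hybrids also within each stage (2 libraries a side), and the hybrid-by-stage interaction with a moderated F test. The gene and list tests of a contrast were two-sided, with Benjamini-Hochberg adjustment over the genes or lists tested and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Errors given with ± are SE for log2 changes and SD over 6 libraries for FPKM.

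In all, 30 gene lists that fit stem growth, stress and other tissues were fixed as name patterns before the data were examined, as were the design and the alternatives except the 3 added fits named last. After the gene names were seen, and before any test, 8 matched names whose synonym belongs to another kind of gene were taken out of the lists. Lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists within a contrast. With the estimated correlation, no list passed in any of the 6 averaged contrasts. The list members that rose or fell were counted from the gene tests over all genes, and also adjusted over the list alone.

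Genes were named by a rule fixed before the data were examined. It took genes past the threshold with the same sign in all 3 stages (or hybrids), a mean FPKM of at least 5 on the higher side and an informative name. Of these, the 5 largest changes each way were named for high against low and for tasseling against jointing, and the 3 largest each way elsewhere. It added the 3 named members with the smallest adjusted p of each list that passed camera, and every tested member of the plant height list with its high against low value. Genes outside the rule are said to be chosen after their values were seen.

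The procedure was tested on simulated values for the same 26792 genes. Genes given a change singly were drawn from those with a mean log2(FPKM + 1) over 2. For high against low over all stages, 46% of 100 genes changed by 1 log2 unit and 89% of 100 genes changed by 2 were recovered. For tasseling against jointing these shares were 47% and 94%. For high against low at jointing alone they were 2% and 53%. For the interaction, 19% of 100 genes changed by 2 and 82% of 100 changed by 4 were recovered. Camera called all 5 simulated lists of 40 genes shifted by 0.3 in high against low, and 0 of 20 unshifted lists, with either correlation. The simulated genes varied independently, while the estimated correlation within the ribosomal protein list was 0.47. These rates may therefore not hold for real lists whose genes move together.

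The alternatives were a pseudocount of 0.1, no filter, median-of-ratios scaling, quantile normalization, the replicate number as a block, robust variance moderation, an added threshold of 1 log2 unit, a fit of only the groups compared, and leaving out each library in turn. Added after seeing the data were a fit with relative depth as a covariate and 2 fits without libraries whose nearest library was of another stage. Of these 4 libraries, high jointing 2 and low big flare 1 were left out in 1 fit and low jointing 2 and high jointing 1 in the other, because without all 4 the high jointing group would be empty. Count-based tests were not used, because the values are not counts. Figures were drawn with matplotlib 3.10.9.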

Results

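Stem transcriptomes were measured in a low, a middle and a high maize hybrid at jointing, big flare and tasseling, with 2 libraries in each of the 9 groups. Of 34474 genes, 26792 were tested, and each library had between 20758 and 22708 genes at 1 FPKM or more. The correlation of log2(FPKM + 1) between replicates was 0.9 in low big flare, 0.901 in high jointing and 0.91 in low jointing, and it reached 0.941 in high big flare and low tasseling. These correlations are across genes, which are not independent replicates. The first principal component held 34.4% of the variance and set the tasseling libraries apart, and the second held 13.6% and separated the low hybrid from the others. High jointing replicate 2 was nearest to high tasseling replicate 2 (r = 0.905), and high jointing replicate 1 to high big flare replicate 1 (0.91). Low big flare replicate 1 and low jointing replicate 2 were nearest to each other (r = 0.914).

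**Figure D1:**
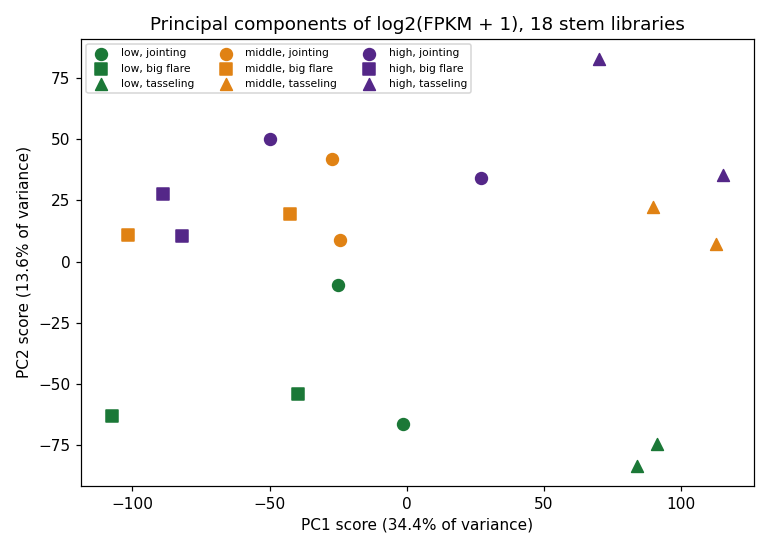
Scores of the 18 libraries on the first (34.4% of variance, x axis) and second (13.6%, y axis) principal components of log2(FPKM + 1); each point is a library, colour gives the hybrid and shape the stage. The 6 tasseling libraries lie at the right and the low hybrid at the bottom, while the 2 high jointing libraries lie apart, at -49.7 and 27.1 on the first component.

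Several genes with large differences between the high and low hybrids were near 0 in one of them at all 3 stages, among genes picked for the same sign at each stage. A peptidyl-prolyl cis-trans isomerase-like gene (Zm00001d050635), of a family that assists protein folding, averaged 331 ± 91.8 FPKM in the high hybrid and 0.547 ± 0.769 in the low hybrid (SD, n = 6). A class I heat shock protein 3 gene (Zm00001d028557), a small chaperone, went the other way, at 1 ± 1.03 FPKM in the high and 209 ± 116 in the low hybrid (n = 6). The low hybrid was also the higher one for a Na+/H+ antiporter (Zm00001d028330) and for the histone-lysine N-methyltransferase SUVR5-like gene (Zm00001d043649). Of the 11 tested members of the plant height list, 0 passed the threshold in limma in high against low, and 0 had an unadjusted p under 0.05. An effect of each member on height was not checked. In middle against low and high against middle, 0 passed over all genes, and 1 and 2 had an unadjusted p under 0.05. Adjusted over the list alone, 1 was higher in the middle than in the low hybrid, and 1 was lower in the high than in the middle hybrid.

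In total, 2468 genes passed the threshold, 960 higher and 1508 lower in the high hybrid (1208 and 1402 with median-of-ratios scaling, 1210 and 1386 with quantile normalization), and 96.1% of them had the same sign at all 3 stages. That share is high partly by selection, since the genes were called on the mean of these stages. Over all genes, the high against low changes correlated between stages at 0.45 to 0.53. The isomerase-like gene was higher by 7.83 ± 0.48 log2 units (adjusted p = 2.8e-07). Also higher were a membrane protein gene (BGI_novel_G000965, 5.23 ± 0.30, adjusted p = 1.5e-07), a translation factor SUI1 homolog (Zm00001d035710, 5.23 ± 0.31, 2.2e-07), a subunit of NADH-ubiquinone oxidoreductase of the respiratory chain (Zm00001d009803, 5.01 ± 0.22, 2.9e-08) and a calcium-dependent protein kinase 8-like gene (Zm00001d011666, 4.47 ± 0.37, 4e-06). All 6 high libraries exceeded every low library for these 5 genes. The heat shock protein gene was lower by 6.72 ± 0.49 (log2 change -6.72, adjusted p = 1.2e-06), the antiporter changed by -5.11 ± 0.18 (5.4e-09) and the SUVR5-like gene by -4.46 ± 0.18 (1.4e-08). All 6 low libraries lay above every high library for these 3 genes. A 40S ribosomal protein S8-like gene (Zm00001d053635) changed by -5.58 ± 0.76 (adjusted p = 0.00033), with 4 low libraries above every high library. It was listed at 0 in 5 high libraries and at 75.01 FPKM in 1 high tasseling library. A lipid-transfer protein gene (Zm00001d023345) averaged 0.398 ± 0.698 FPKM in the high and 289 ± 416 in the low hybrid, with 4 low libraries above every high library (log2 change -5.18, adjusted p = 0.022). Its adjusted p rose to between 0.052 and 0.067 when any of 7 libraries was left out (low jointing 1, low big flare 1, low tasseling 1, high jointing 1, high big flare 1 and 2, high tasseling 2).

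Among the members of the plant height list, the gibberellin synthesis gene d3 (cytochrome P450 88A1, Zm00001d045563) averaged 29.5 ± 20.6 FPKM in the high and 80.2 ± 78.4 in the low hybrid, a log2 change of -0.96 ± 0.61 (adjusted p = 0.4). The gibberellin 3-oxidase Dwarf1 (Zm00001d039634) gave -0.72 ± 0.61 (0.55), the ent-copalyl diphosphate synthase an2 (Zm00001d029648) 0.51 ± 0.51 (0.62) and the DELLA gene d9 (Zm00001d013465) -0.01 ± 0.20 (0.99). The brassinosteroid genes na1 (steroid reductase DET2, Zm00001d042843) and CYP85A1 (Zm00001d033180) gave -0.48 ± 0.26 (0.32) and 0.01 ± 0.41 (1). The phytochrome genes PhyB1 (Zm00001d028905) and PhyB2 (Zm00001d047632) gave -0.02 ± 0.14 (0.97) and -0.08 ± 0.17 (0.84). The values for ct2 (Zm00001d027886), liguleless2 (Zm00001d042777) and PIN1d (Zm00001d052442) were 0.02 ± 0.18 (0.97), -0.20 ± 0.35 (0.8) and 0.09 ± 0.30 (0.9). A change of 1 log2 unit was recovered for 46% of simulated genes in this comparison, so differences of 1 log2 unit or less may have gone undetected here. Larger ones may have too for d3 and Dwarf1, where the SE was 0.61.

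Camera passed 0 of 30 gene lists in high against low, with 7 at an unadjusted p under 0.05. The lowest adjusted p was 0.0568, shared by 5 lists: lignin biosynthesis (4 of 35 members higher, 1 lower), pathogenesis-related genes (5 of 65 higher), photosynthesis (51 of 70 above 0, 1 past the threshold and lower), cell division and replication (1 of 35 higher, 3 lower) and ribosomal proteins (8 of 232 higher, 18 lower). The direction was up for the first 3 and down for the last 2. Adjusted over the list alone, these counts were 5 and 1, 5, 0, 1 and 3, and 8 and 18. With an estimated correlation the adjusted p was 0.997 for each. The number of lists past the threshold was 6 without low big flare 1 or low tasseling 1, and 5 without high tasseling 1, middle jointing 1 or middle jointing 2. It was 4 without high big flare 2, 3 without low jointing 2, 2 without high jointing 2 and 1 without low big flare 2 or high jointing 1.

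The middle hybrid shared several of these differences from the low hybrid. The NADH-ubiquinone oxidoreductase subunit (5.19 ± 0.22, adjusted p = 2.3e-08) and the membrane protein gene BGI_novel_G000965 (5.24 ± 0.30, 1.5e-07) were higher in the middle than in the low hybrid. The class I heat shock protein 3 gene (-6.59 ± 0.49, 1.7e-06) and the Na+/H+ antiporter (-5.30 ± 0.18, 6.8e-09) were lower. A gene matching a cysteine protease (BGI_novel_G000791) averaged 52.5 ± 30.4 FPKM in the middle hybrid and was listed at 0 in all 6 low libraries (adjusted p = 2.6e-07). The wound-induced proteinase inhibitor WIP1 (Zm00001d040029) was lower in the middle hybrid, at 13.8 ± 11.5 against 1010 ± 991 FPKM (log2 change -5.12 ± 1.01, adjusted p = 0.0072). Middle against low gave 1856 genes, 702 higher and 1154 lower. Photosynthesis genes stood higher in the middle hybrid as a list (64 of 70 above 0, median change 0.58, adjusted p = 1.06e-08), but the adjusted p was 0.993 with an estimated correlation. Of its members, 2 rose over all genes and 1 adjusted over the list alone. An oxygen-evolving complex gene (Zm00001d027422) rose by 0.98 ± 0.25 (adjusted p = 0.031), which was lost, at 0.062 to 0.087, without any of 7 libraries (low big flare 1, both low tasseling, middle jointing 2, middle big flare 2, both middle tasseling). The chloroplast rbcL match (Zm00001d045698, adjusted p = 0.015) was listed above 0 in the 2 middle big flare libraries alone, at 5.14 and 23.91 FPKM. Its call was lost, with the change still at 1.21 (adjusted p = 0.05), without high jointing 2 and low big flare 1 together. Photosystem I subunit XI (Zm00001d039687) gave 1.16 ± 0.33 (adjusted p = 0.054), which passed without low jointing 2 (0.0081) or either high big flare library (0.039). The number of lists was 9 without low big flare 1, 6 without middle big flare 1, 3 without low jointing 2 and 2 without low tasseling 1 or middle tasseling 1.

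Of the genes that passed in both comparisons with the low hybrid, 1003 had the same sign, 226 higher and 777 lower than in the low hybrid, and 10 had opposite signs. Both comparisons use the low libraries. Simulated unchanged groups shared 0.05 genes, but with no difference simulated hardly any gene can pass either comparison, so that value is no baseline for 1003. Independent lists would share 90, and with the low libraries split between the comparisons 617.5 genes were shared on average. The correlation of the log2 changes across genes was 0.646, against 0.503 simulated with no effect and 0.413 with split low libraries, and the covariance was 0.2543 against 0.0476.

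High against middle gave 1190 genes, 635 higher and 555 lower in the high hybrid. The ascorbate peroxidase APx2 gene (Zm00001d007569), which removes hydrogen peroxide, averaged 43.7 ± 14.4 FPKM in the high and 0.158 ± 0.388 in the middle hybrid (log2 change 5.26 ± 0.24, adjusted p = 7.9e-08). A sterol isomerase gene (Zm00001d040196) was higher by 4.61 ± 0.20 (7.6e-08), and a mini zinc finger protein 1-like gene (Zm00001d023289) averaged 21.6 ± 11.6 FPKM in the high hybrid and was listed at 0 in all 6 middle libraries (5.6e-05). An actin-depolymerizing factor 2-like gene (Zm00001d034326) was lower in the high hybrid (-5.08 ± 0.18, 2.6e-08), as was the cysteine protease match BGI_novel_G000791 (-4.55 ± 0.33, 2.6e-06). A pectinesterase 21 gene (Zm00001d016907) gave -4.58 ± 1.19 (adjusted p = 0.049), a call lost with a pseudocount of 0.1 (0.11), with no filter (0.071), with relative depth as a covariate (-4.16 ± 1.23, 0.1) and, at 0.062 to 0.12, without any library other than middle big flare 1 and middle tasseling 2. The photosynthesis list was lower in the high hybrid (6 of 70 members above 0, median change -0.36, adjusted p = 0.00168; adjusted p = 0.916 with an estimated correlation). A single member, the rbcL match, passed over all genes (adjusted p = 0.021) and adjusted over the list alone. It was listed at 0 in all high libraries, and the call was lost, at 0.05 to 0.054, without high jointing 1, high big flare 1 or 2, high tasseling 2, middle jointing 1 or middle tasseling 1 or 2. Photosystem I subunit N (Zm00001d023713) and Zm00001d027422 gave -1.41 ± 0.41 (0.082) and -0.83 ± 0.25 (0.085). The former passed without middle jointing 1 (0.0073) and the latter without low jointing 1 (0.017) or 2 (0.018). The number of lists was 0 without high big flare 2 or middle jointing 2, and 2 without high jointing 2, middle big flare 2 or middle tasseling 2.

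The hybrids are ordered by height, and few genes were called in that order in both steps. Of the genes past the threshold in both middle against low and high against middle, 22 changed the same way in both steps (10 rising and 12 falling with height), while 261 were highest and 145 lowest in the middle hybrid. Independent lists would give 41 and 42 for ordered and unordered genes. Simulation with no effect gave 0 of each, but hardly any simulated gene can pass either step, so it is no baseline for these counts. Both steps use the middle libraries, which favours unordered genes. Without low tasseling replicate 1 the ordered count was 14.

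Within stages, high against low gave 627, 779 and 1459 genes at jointing, big flare and tasseling, middle against low 506, 647 and 684, and high against middle 333, 431 and 325. The larger number for high against low at tasseling came with a shift of all genes: the median change from low to high was -0.23 log2 units there (-0.12 from middle to high). The scaling alternatives that removed the shift turned 519 higher and 940 lower genes into 702 and 651 (median-of-ratios) or 677 and 672 (quantile). The number at tasseling stayed the largest, at 1353 (median-of-ratios) and 1349 (quantile). High against low gave 713 with either scaling at jointing, and 794 and 809 at big flare. These counts rest on 2 libraries a side with the spread borrowed from all groups. Fitted on the 4 libraries compared, limma gave 3, 0 and 0 genes at jointing, 0, 0 and 0 at big flare, and 248, 357 and 0 at tasseling for middle against low, high against low and high against middle. At an unadjusted p under 0.05 these were 2187, 2108 and 1785, then 2282, 2582 and 2340, then 3847, 5137 and 2127. High against low at tasseling was 673, 506 and 491 without low replicate 1, low replicate 2 and high replicate 2. At jointing, high against low was 352 without low 1 and 359 without high 1. Middle against low was 261, 309 and 276 there without low 1, middle 1 and middle 2. High against middle was 210, 188, 194 and 169 without high 1, high 2, middle 1 and middle 2. At big flare, high against low was 491, 506 and 469 without low 1, low 2 and high 2. Middle against low was 420 and 363 there without low 2 and middle 2. High against middle was 272, 213, 233 and 232 without high 1, high 2, middle 1 and middle 2. At tasseling, middle against low was 448, 350, 363 and 378 without low 1, low 2, middle 1 and middle 2. High against middle was 203, 175 and 186 without high 2, middle 1 and middle 2.

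**Figure D2:**
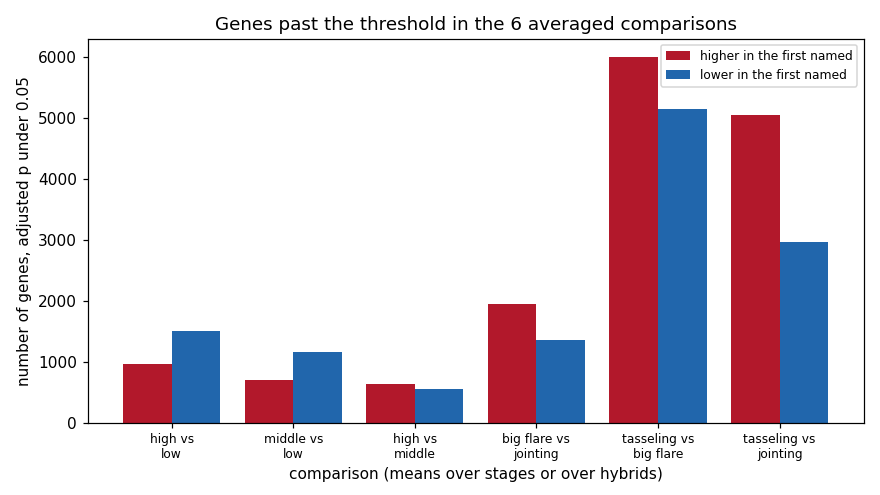
Number of genes with an adjusted p under 0.05 (y axis) in the 6 averaged comparisons (x axis), as bars for genes higher and lower in the group named first. The stage comparisons with tasseling, at 6002 and 5144 and at 5050 and 2965 genes, exceed the hybrid comparisons.

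From jointing to big flare, 19 of 79 heat shock genes fell and 7 rose, 7 of 25 secondary wall and xylem genes fell and 2 rose, and 14 of 33 floral MADS-box genes rose and 1 fell. Each of these lists had an adjusted p of 0.405 with an estimated correlation. Of all genes tested, 12.4% passed in this step in either direction. The xylem cysteine proteinase 2 gene (Zm00001d035689), a protease of maturing xylem vessels, fell from 171 ± 135 to 2.22 ± 2.87 FPKM (SD, n = 6). The heat shock protein 82 gene (Zm00001d024903), a chaperone, fell from 45.8 ± 32 to 2.84 ± 3.16 FPKM. The gene for the MYB-like transcription factor ETC3 (Zm00001d044194), of a small family that acts on epidermal cell fate, rose from 15.3 ± 18.6 to 598 ± 383 FPKM, and a gene that matches MADS15 (Zm00001d034045) rose from 27.8 ± 11.5 to 171 ± 89.4.

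This step gave 3310 genes, 1954 higher and 1356 lower at big flare, of which 95.9% had the same sign in all 3 hybrids. With median-of-ratios scaling the split became 1415 higher and 1769 lower. ETC3 rose by 5.59 ± 0.52 (adjusted p = 0.00029), the glutathione transferase GSTU6 (Zm00001d029706) by 4.21 ± 0.56 (0.0014) and the cysteine endopeptidase vignain (Zm00001d031971) by 3.99 ± 0.58 (0.0021). Xylem cysteine proteinase 2 changed by -5.50 ± 0.74 (0.0014), a lipid-transfer protein AKCS9 gene (Zm00001d038913) by -4.52 ± 0.49 (0.00047) and a leucine-rich repeat protein gene (Zm00001d026576) by -4.30 ± 0.82 (0.0072). The count was 1593 without low big flare replicate 2, 1633 without middle big flare replicate 1, 1788 without middle jointing replicate 2, 1866 and 2110 without high big flare replicates 2 and 1, and 2140 without high jointing replicate 2.

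Floral MADS-box genes rose as a list between jointing and big flare: 14 of 33 members rose and 1 fell (17 and 2 adjusted over the list alone), with an adjusted p of 0.000336 and an adjusted p of 0.405 with an estimated correlation. Zm00001d034045 and Zm00001d013259, which match isoforms of the same protein MADS15, rose by 2.54 ± 0.26 (0.00047) and 2.04 ± 0.28 (0.0016), and m21 (Zm00001d044899) by 1.26 ± 0.17 (0.0016). Of the heat shock list, 7 of 79 members rose and 19 fell (7 and 22 adjusted over the list alone; list adjusted p = 0.000168, and 0.405 as the adjusted p with an estimated correlation). Heat shock protein 82 changed by -3.65 ± 0.49 (0.0015) and a class II small heat shock protein (Zm00001d039566) by -2.05 ± 0.29 (0.0018), while heat shock factor protein 4 (Zm00001d020714), a transcription factor, rose by 1.95 ± 0.23 (0.00079). The ribosomal protein list, built from names for cytosolic proteins but with some organellar matches, passed upward (3 of 232 rose, 1 fell; 0 and 1 adjusted over the list alone; adjusted p = 0.0251, and adjusted p = 0.712 with an estimated correlation). Its leading members went both ways: L18A (Zm00001d039619) changed by -2.48 ± 0.43 (0.0046) and L31 (Zm00001d031429) by 0.98 ± 0.24 (0.022, lost at 0.057 to 0.068 without low jointing 2, low big flare 2, high big flare 2, middle jointing 2 or middle big flare 1). The plastid L2 match BGI_novel_G000659, 1 of the 3 that rose (adjusted p = 0.035), was listed at 0 in all jointing libraries and above 0 in 2 big flare libraries, and it lost the call, at 0.058 to 0.085, without any jointing library or without high big flare 1 or 2 or middle big flare 1 or 2.

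Of 25 secondary wall and xylem genes 7 fell and 2 rose (11 and 2 adjusted over the list alone; list adjusted p = 0.000264), of 16 cellulose synthase genes 2 fell (5 alone; 0.000714), of 29 expansin genes 7 fell and 2 rose (8 and 2 alone; 0.000714), and of 45 pectin-modifying genes 6 fell (6 alone; 0.000624). With an estimated correlation the adjusted p was 0.405, 0.405, 0.506 and 0.405. The secondary wall NAC factor 7 (Zm00001d045600), a regulator of wall thickening, changed by -1.75 ± 0.36 (0.01), cellulose synthase 3 (Zm00001d039660) by -0.76 ± 0.15 (0.0082) and expansin-like 3 (Zm00001d029783) by -1.45 ± 0.18 (9e-04). An endo-1,4-beta-xylanase (Zm00001d039958) rose by 2.96 ± 0.56 (0.0069). The calls for cellulose synthase 6 (Zm00001d034770, -0.91 ± 0.21, 0.017), expansin-B7 (Zm00001d027283, -2.31 ± 0.55, 0.019), beta-expansin 7 (Zm00001d029906, 3.67 ± 0.89, 0.021), polygalacturonase Zm00001d044110 (-1.68 ± 0.41, 0.021) and pectinesterase 15 (Zm00001d019753, -1.08 ± 0.27, 0.024) were each lost when single libraries were left out. For cellulose synthase 6 these were low big flare 2, high big flare 1 and middle big flare 1 (0.052 to 0.056), and for expansin-B7 low big flare 2, high big flare 1 and middle jointing 2 (0.052 to 0.053). For beta-expansin 7 they were low jointing 2, high big flare 2 and middle jointing 2 (0.051 to 0.058), and for the polygalacturonase low jointing 1, low big flare 2, high big flare 1, middle jointing 2 and middle big flare 1 (0.051 to 0.059). For pectinesterase 15 they were low jointing 1, low big flare 2, high jointing 2, high big flare 1, middle jointing 1 and middle big flare 1 (0.052 to 0.068). The pectinesterase inhibitor Zm00001d016741 (0.021), listed at 0 in all 6 big flare libraries, lost its call without low big flare 2, high jointing 2, high big flare 2 or middle big flare 1 (0.052 to 0.059). The CesA-8 match Zm00001d005478 gave -1.05 ± 0.32 (0.05), and it passed with median-of-ratios (0.028) or quantile (0.029) scaling, narrowly with robust variance moderation (0.05), and without low big flare 1 (0.0083), middle big flare 2 (0.027) or either high tasseling library (0.048).

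Further lists passed downward in this step. Aquaporins, the water channels, had 7 of 27 members lower and 2 higher (11 and 2 adjusted over the list alone; adjusted p = 0.00101, and adjusted p = 0.405 with an estimated correlation), among them PIP1-3/PIP1-4 (Zm00001d051403, -1.44 ± 0.25, 0.0046), PIP2-2 (Zm00001d005421, -1.74 ± 0.31, 0.0049) and NIP3-1 (Zm00001d032461, -1.32 ± 0.25, 0.0077). Jasmonate genes had 6 of 39 lower and 5 higher (11 and 5 alone; adjusted p = 0.00595, 0.405 estimated): allene oxide synthase 1 (Zm00001d013185) changed by -1.29 ± 0.19 (0.0021) and lox4 (Zm00001d033624) by -1.63 ± 0.34 (0.011), while opr6 (Zm00001d040842) rose by 2.58 ± 0.52 (0.0094). Pathogenesis-related genes had 5 of 65 lower and 1 higher (5 and 0 alone; adjusted p = 0.00101, 0.405 estimated), with the glucan endo-1,3-beta-glucosidase genes Zm00001d022059 (-2.29 ± 0.38, 0.0037), Zm00001d043361 (-0.92 ± 0.20, 0.013) and Zm00001d033423 (-1.86 ± 0.45, 0.02, lost at 0.059 to 0.063 without low big flare 2, middle jointing 2 or middle big flare 1). Photosynthesis genes had 5 of 70 lower and 1 higher (2 and 1 alone; adjusted p = 0.000368, 0.607 estimated). They include Zm00001d027422 (-1.41 ± 0.25, 0.0048) and the Rubisco small chain (Zm00001d052595, -1.60 ± 0.39, 0.022, lost at 0.052 to 0.068 without high big flare 2, middle jointing 2 or middle big flare 1), while the rbcL match Zm00001d045698 was listed at 0 at jointing. The anther list passed (adjusted p = 0.0174, 0.405 estimated) with 0 of 34 members past limma's threshold over all genes or adjusted over the list alone, and 7 at an unadjusted p under 0.05. Its leading members match the protein APG, a name that GDSL-type lipases also carry, so they need not be anther markers. They are Zm00001d019855 (-1.56 ± 0.53, 0.073), Zm00001d032788 (-2.09 ± 0.76, 0.094) and Zm00001d043458 (-2.13 ± 0.84, 0.12). The first passed without low jointing 1 (0.043), high big flare 2 (0.047) or middle jointing 1 (0.048), the second without high big flare 2 (0.045) and the last without low big flare 1 (0.034) or high jointing 1 (0.042).

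From big flare to tasseling, 27 of 44 histone, 17 of 35 cell division and 22 of 45 pectin-modifying genes rose (2, 3 and 4 fell), and 6 of 11 meristem homeobox genes fell (1 rose). Each of these lists had an adjusted p of 0.681 with an estimated correlation. Of all genes tested, 41.6% passed in this step in either direction, so list members that rose or fell are to be read against that share. Xylem cysteine proteinase 2 returned to 206 ± 150 FPKM, and a histone H2A gene (Zm00001d047787) rose from 37.4 ± 12.6 to 329 ± 158 FPKM (SD, n = 6). The polygalacturonase gene Zm00001d023813, whose product cuts pectin, rose from 11 ± 3.87 to 104 ± 16.1 FPKM. The homeobox gene knotted-1-like 11 (Zm00001d046568), of a family that maintains meristems, fell from 101 ± 24.6 to 25 ± 6.35, and benzoxazinless1 (Zm00001d048709), the first enzyme of benzoxazinoid defence compounds, fell from 353 ± 120 to 8.94 ± 10.8.

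This step gave the most genes, 11146, with 6002 higher and 5144 lower at tasseling and 96.3% of the same sign in all 3 hybrids. With quantile normalization more were lower (6149) than higher (5575). With relative depth as a covariate, chosen after seeing the data, the count was 7347. Among genes that met the naming rule, the largest rises were those of a cortical cell-delineating protein gene (Zm00001d002721, 6.96 ± 0.61, adjusted p = 1.6e-05), a putative DNA helicase homolog (Zm00001d023344, 6.36 ± 0.79, 8.8e-05) and a glutathione transferase (Zm00001d027540, 6.19 ± 1.11, 0.00085). The largest falls among them were those of ETC3 (-6.12 ± 0.52, 1.6e-05), benzoxazinless1 (-5.57 ± 0.34, 7.5e-06) and the chaperone regulator BAG 6 (Zm00001d016070, -5.37 ± 0.61, 5.2e-05). All 6 libraries of the higher stage exceeded every library of the lower stage for these 6 genes.

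Of 44 histone genes 27 rose and 2 fell (the same numbers adjusted over the list alone; list adjusted p = 0.000513), and of 35 cell division and replication genes 17 rose and 3 fell (18 and 3 alone; 0.0215). With an estimated correlation the adjusted p was 0.681 for both. The H2A genes Zm00001d047787 and Zm00001d044246 rose by 3 ± 0.35 (5.8e-05) and 1.94 ± 0.22 (5.1e-05), and H2B.1 (Zm00001d051591) by 3.49 ± 0.30 (1.6e-05) over the hybrids, with values in high near 0 throughout. The origin recognition complex subunit 6 (Zm00001d022226) rose by 2.01 ± 0.32 (4e-04), and the replication clamp genes pcna2 (Zm00001d051995) and PCNA (Zm00001d018415) by 2.08 ± 0.37 (0.00087) and 1.85 ± 0.35 (0.0013). Of 232 ribosomal protein genes 76 rose and 11 fell (74 and 11 alone; adjusted p = 0.00802, and adjusted p = 0.729 with an estimated correlation), among them L12 (Zm00001d051543, 1.89 ± 0.26, 0.00018), L18A (Zm00001d039619, 3.27 ± 0.43, 0.00012) and a gene that encodes a fusion of succinate dehydrogenase and ribosomal protein S14 (Zm00001d035136, 1.34 ± 0.16, 6e-05).

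Of 45 pectin-modifying genes 22 rose and 4 fell (23 and 4 adjusted over the list alone; adjusted p = 0.00253), of 25 secondary wall and xylem genes 11 rose and 4 fell (11 and 4 alone; 0.0417), and of 16 cellulose synthase genes 7 rose and 1 fell (7 and 1 alone; 0.0248). With an estimated correlation the adjusted p was 0.681 for each. Polygalacturonase Zm00001d023813 rose by 3.17 ± 0.27 (1.6e-05), pectinesterases Zm00001d022460 and Zm00001d008334 by 3.84 ± 0.48 (9.8e-05) and 2.79 ± 0.36 (0.00012). The cellulose synthases Zm00001d005478, Zm00001d034770 and Zm00001d037636 rose by 2.36 ± 0.32 (0.00014), 1.46 ± 0.21 (0.00022) and 1.68 ± 0.26 (0.00036). Xylem cysteine proteinase 2 rose by 6.09 ± 0.74 (7.4e-05), the xylem cysteine proteinase 1-like gene (Zm00001d017834) by 1.82 ± 0.29 (0.00043) and the secondary wall NAC factor 2 (Zm00001d049678) by 2.43 ± 0.37 (0.00028). Aquaporins had 13 of 27 higher and 1 lower (16 and 2 alone; adjusted p = 0.0215, 0.681 estimated): TIP2-2 (Zm00001d017485), SIP2-1 (Zm00001d028951) and a PIP2-2-like gene (Zm00001d019563) rose by 2.46 ± 0.32 (0.00012), 1.11 ± 0.15 (0.00015) and 1.92 ± 0.29 (0.00026).

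Pathogenesis-related genes had 31 of 65 higher and 8 lower (32 and 9 adjusted over the list alone; adjusted p = 0.00153, and adjusted p = 0.681 with an estimated correlation), led by the glucan endo-1,3-beta-glucosidase gene Zm00001d022059 (3.63 ± 0.38, 3.6e-05), which can act on the wall, and the thaumatin-like genes Zm00001d019150 (3.28 ± 0.32, 2.9e-05) and Zm00001d006054 (2.13 ± 0.25, 6e-05). The gibberellin response list had 15 of 26 higher and 4 lower (15 and 5 alone; adjusted p = 0.0461, 0.681 estimated). Its leading members Zm00001d016895, Zm00001d020737 and Zm00001d037288, at 2.08 ± 0.22 (3.6e-05), 1.71 ± 0.19 (4.6e-05) and 1.54 ± 0.24 (0.00035), match a receptor GID1L2 name that carboxylesterase-like proteins also carry. Of 11 meristem homeobox genes 6 fell and 1 rose (the same alone; adjusted p = 0.0215, 0.681 estimated): knotted-1-like 11 by -1.98 ± 0.20 (3.2e-05), knox3 (Zm00001d033861) by -4.04 ± 0.59 (0.00023) and rough sheath 1 (Zm00001d007842) by -1.51 ± 0.24 (0.00038). Of 33 floral MADS-box genes 10 fell and 5 rose (the same alone; adjusted p = 0.0248, 0.681 estimated), including MADS-box genes Zm00001d025479 (-3.50 ± 0.28, 1.3e-05), Zm00001d027957 (-1.89 ± 0.16, 1.6e-05) and m21 (-1.98 ± 0.17, 1.6e-05).

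From jointing to tasseling, 31 of 79 heat shock and 16 of 70 photosynthesis genes fell (8 and 1 rose), and 99 of 232 ribosomal protein and 25 of 44 histone genes rose (0 and 1 fell). Each of these lists had an adjusted p of 0.912 with an estimated correlation. Of all genes tested, 29.9% passed in this comparison in either direction. Benzoxazinless1 fell from 715 ± 312 to 8.94 ± 10.8 FPKM (SD, n = 6), and the laccase lac5 (Zm00001d042901), of a family that polymerizes lignin, from 700 ± 430 to 35.8 ± 40.7. A MADS-box transcription factor gene (Zm00001d018667) rose from 1.22 ± 1.7 to 85.3 ± 25.8 FPKM, and an arabinogalactan protein gene AGP20 (Zm00001d010434) from 1.58 ± 1.42 to 73.1 ± 31.7.

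This comparison gave 8015 genes, 5050 higher and 2965 lower at tasseling, and 95.4% had the same sign in all 3 hybrids. With quantile normalization the split was 4373 higher and 3957 lower, and with relative depth as a covariate the count was 5073. The MADS-box gene rose by 5.57 ± 0.44 (adjusted p = 3.4e-05), the proline-rich protein genes Zm00001d028405 and Zm00001d047934 by 5.28 ± 0.56 (1e-04) and 4.86 ± 0.51 (9.9e-05), and AGP20 by 4.91 ± 0.44 (4.7e-05). A dihydroflavonol reductase gene (Zm00001d020958) rose by 4.44 ± 0.56 (0.00025). Benzoxazinless1 changed by -6.53 ± 0.34 (3e-06), a class I heat shock protein 3 gene (Zm00001d028561) by -5.65 ± 0.62 (0.00012), and BAG 6 by -5.40 ± 0.61 (0.00014). The laccase lac5 changed by -4.82 ± 0.87 (0.0018) and a class I heat shock protein 1 gene (Zm00001d039935) by -4.80 ± 0.42 (4.3e-05).

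**Figure D3:**
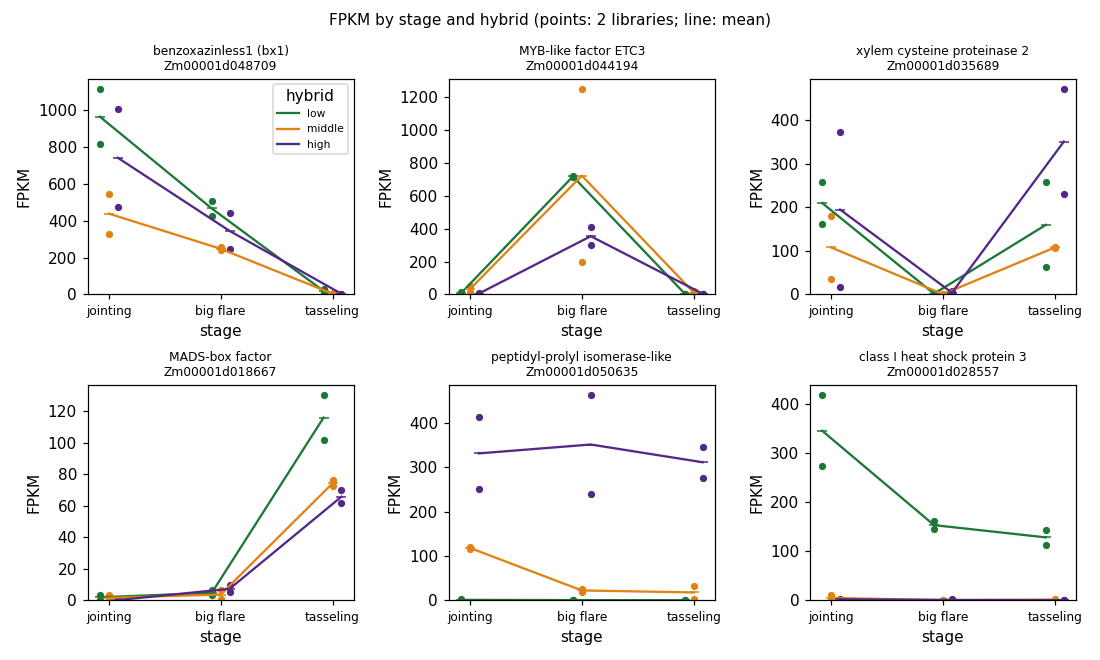
FPKM (y axes, from 0) of 6 genes by stage (x axis) and hybrid (colours), with the 2 libraries of each group as points and lines through the group means. Benzoxazinless1 declines over the stages to 8.94 FPKM on average, ETC3 peaks at big flare, xylem cysteine proteinase 2 is lowest there, and the 2 lower right panels show genes expressed in some hybrids only.

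Of 232 ribosomal protein genes 99 rose and 0 fell in limma (107 and 2 adjusted over the list alone, and 124 and 4 at an unadjusted p under 0.05; list adjusted p = 3.56e-07), of 44 histone genes 25 rose and 1 fell (25 and 2 alone; 1.31e-05) and of 35 cell division and replication genes 16 rose (16 alone; 0.00206). Of 79 heat shock genes 31 fell and 8 rose (33 and 9 alone; 3.23e-05), and of 70 photosynthesis genes 16 fell and 1 rose (11 and 1 alone; 8.68e-05). With an estimated correlation the adjusted p was 0.912 for all 5 lists. Among the examples, ribosomal L38e (Zm00001d031701) rose by 1.98 ± 0.28 (0.00048), and the succinate dehydrogenase and S14 fusion genes Zm00001d049649 and Zm00001d035136 by 1.41 ± 0.16 (0.00015) and 1.13 ± 0.16 (0.00043). A histone H2A gene (Zm00001d044246) rose by 1.80 ± 0.22 (2e-04), and a centromeric H3-like histone (Zm00001d016723) by 1.99 ± 0.27 (0.00041). A histone H1 gene (Zm00001d045478) changed by -1.85 ± 0.27 (0.00055). The origin recognition complex subunit 6, pcna2 and PCNA genes rose by 2.09 ± 0.32 (0.00074), 1.77 ± 0.37 (0.0042) and 1.63 ± 0.35 (0.0048). The class I heat shock protein 1 genes Zm00001d039935 and Zm00001d039936 changed by -4.80 ± 0.42 (4.3e-05) and -4.62 ± 0.46 (8.8e-05), and Zm00001d039566 by -2.77 ± 0.29 (9.9e-05). Photosystem genes Zm00001d005996, Zm00001d049650 and psbH (GRMZM5G831399) changed by -1.72 ± 0.38 (0.005), -1.27 ± 0.29 (0.0065) and -2.87 ± 0.69 (0.0085). With relative depth as a covariate Zm00001d049650 kept its change but lost the call as its SE grew (-1.23 ± 0.43, 0.065). The psbH change shrank to -0.63 ± 0.41 (0.32), so its value above went with library depth, and the cause was not tested.

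Stage changes were shared between hybrids. The log2 changes from big flare to tasseling correlated across genes between hybrids at 0.71 to 0.81, and those from jointing to big flare at 0.53 to 0.59. The hybrid-by-stage interaction passed for 15 genes, with 1335 at an unadjusted p under 0.05. Of the genes named by the rule, histone H2B.1 (Zm00001d051591) was past it (adjusted p = 0.03), at 109 ± 43.3 and 164 ± 115 FPKM in low and middle tasseling (SD, n = 2) and listed at 0 in both high tasseling libraries. The interaction count was 7 without either middle big flare replicate and 82 with no filter on low genes.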

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

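Chosen only after the result was seen were the tests of scaling, of meristem tissue, of replicate depth and of exchanged libraries, and the fit with relative depth. The interaction of hybrid and stage was tested directly and passed for 15 genes, so their stage changes on the log2(FPKM + 1) scale differed between hybrids. One of them is histone H2B.1 (Zm00001d051591, adjusted p = 0.03), at 1.12 and 109 FPKM in low big flare and tasseling, 4.11 and 164 in middle, and listed at 0 in all 4 high libraries of these stages. Zm00001d048770, chosen after its values were seen, was listed at 0 in all middle and high libraries. For genes near 0 throughout a hybrid, the interaction cannot be told apart from a difference in whether that hybrid expresses the gene. Named after their values were seen, 3 HARBI1 nuclease matches (BGI_novel_G000490, BGI_novel_G000492 and BGI_novel_G000495) averaged 23.7, 22.3 and 14.9 FPKM in middle big flare and at most 0.345 in other groups.

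The first pattern is genes with at least 2 FPKM in both libraries of a hybrid and at most 0.5 in both of another at tasseling, 1149 over the 3 hybrid pairs and both directions. A gene can be counted in more than 1 pair, so this number and those below are cases of a gene in a pair, which are not independent. Reads assigned to a near-identical copy would need copies that change the opposite way. Of the 433 cases with a tested copy of the same best protein match, 8.5% had a copy called the opposite way. The copies were called on the mean of the 3 stages, while the genes were picked at tasseling alone. A copy that changed at tasseling only, or by little on a high level, could be missed. The low share therefore does not exclude reads moved from one copy to another. A copy changed the same way for 52.4%, and reads split between copies could also give this, so such splitting is not tested. Copies were taken from shared protein matches rather than sequence, and the remaining genes had no copy to test. Parental alleles that are missing or differ from the reference should stay near 0 at every stage. Of the 550 cases also on at the other stages, 70.2% stayed at 0.5 or less in all 4 other libraries, between the bounds set beforehand. All hybrids share a parent, so in the hybrid near 0 the allele of the shared parent must also give few or no assigned reads. A missing allele in the parent that differs is therefore not enough by itself. Missing alleles and differences in regulation cannot be told apart without parental sequence.

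The second pattern is the 11146 genes that changed between big flare and tasseling. With relative depth as a covariate, 61% of them stayed past the threshold with the same sign, although SEs grew 1.54-fold at the median, which argues against depth as the whole cause. After quantile normalization 95.6% stayed, which argues against scaling. A larger share of dividing meristem in the big flare libraries was predicted to leave cell division and histone genes lower at tasseling. The median of 79 such genes was instead 0.75 higher (0.86, 0.82 and 0.48 in low, middle and high). That argues against a larger share of dividing cells of all kinds at big flare. These genes do not tell meristem from other dividing cells, and homeobox and MADS-box genes fell, so a larger share of meristem is not excluded. Stage itself, which the design names, stays open, as does the position of the internode sampled, which was not tested.

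The third pattern is the weak agreement of replicates in high jointing (0.901) and low big flare (0.9). Replicates at different points of the stage change may explain it: the replicate difference correlated across genes with the big flare to tasseling change of the other hybrids at -0.47 in high jointing and 0.4 in low big flare. The same was seen in middle big flare (-0.4, agreement 0.917) and in high tasseling (0.39, agreement 0.938), and not in low jointing (0.05), the next weakest (0.91), which it leaves unexplained. A depth difference is argued against in low big flare, where the replicates differed 1.15-fold (median of the groups 1.24), and stays open in high jointing (1.82-fold, the largest), although low and middle tasseling differed 1.61 and 1.49-fold and agreed at 0.941 and 0.934. An exchange of high jointing replicate 2 with a high tasseling library is argued against, since the 2 high tasseling libraries correlated at 0.938 and high jointing replicate 1 with the nearer of them at 0.855.

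Other splits of the libraries, exchanged within stages or within hybrids (100 of 108 for each contrast), test whether chance groupings give as much. For gene counts, only the real split, 1 of 100, reached the real value in each of the 6 averaged contrasts: 2468 against a highest other of 517 (high and low), 1856 against 488 (middle and low), 1190 against 97 (high and middle), 3310 against 80 (jointing and big flare), 11146 against 5542 (big flare and tasseling) and 8015 against 4775 (jointing and tasseling). Most other splits part the replicates of a group, which adds group differences to the spread and lowers their counts. The splits therefore show that libraries of a group resemble each other. They cannot exclude chance differences between plants, since the 2 libraries of a group may be technical. The 5542 and 4775 came from splits that part the replicates of some groups, and splits that kept replicates together reached at most 750 and 72. Splits of the 3 hybrids at once cannot test the overlap of 1003 (highest other 50, 1 of 100 splits), since the other splits called at most 50 genes in the smaller of the 2 comparisons. They gave 0 ordered genes against 22 (1 of 100), but had at most 53 genes past both steps against the real 428, so they do not test the order, and 22 is below the 41 of independent lists. For lists in high against low the splits test nothing, since every split (100 of 100) passes at least the real 0 (highest other 17). For the number of lists elsewhere, chance is not excluded: 96 and 95 of 100 splits passed as many as the real 1 and 1 of middle against low and high against middle (highest other 17 and 13). For the stage contrasts 18, 22 and 57 of 100 splits passed as many as the real 12, 11 and 5 (highest other 16, 17 and 13).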

How the results depend on the processing

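Relative depth and 2 fits without libraries nearest to another stage were chosen after seeing the data. Of the 4 such libraries, high jointing 2 and low big flare 1 were left out first, and low jointing 2 and high jointing 1 in the other fit. Without all 4 high jointing would be empty. Of 125 named gene results past the threshold, 108 kept it with the same sign in every fit that gave a value, 17 lost it in some fit (14 with a single library left out), and 0 reversed. A gene under the filter without a library gave no value there. No list that passed changed the sign of its median with scaling. Low depth limits genes near the filter.

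The counts moved as follows, and where nothing is said of the cause it was not tested. With no filter the interaction gave 82 genes, and with quantile normalization 1 list passed in high against low. An added threshold of 1 log2 unit, which removes genes by construction, left 1614 genes for high against low, 1708 for jointing to big flare, 6104 for big flare to tasseling and 3840 for jointing to tasseling. A fit of only the groups compared has 2 residual degrees of freedom within a stage and gave, for middle against low, high against low and high against middle, 3, 0 and 0 genes at jointing, 0, 0 and 0 at big flare, and 248, 357 and 0 at tasseling. With an estimated correlation 0 lists passed in every contrast, against 1 and 1 for middle against low and high against middle and 12, 11 and 5 for the stage steps. With relative depth as a covariate the counts were 7347 (big flare to tasseling), 5073 (jointing to tasseling) and 174 (high against middle at jointing), with 2 lists for high against low, 7 for big flare to tasseling and 9 for jointing to tasseling. Without high jointing 2 and low big flare 1 they were 149 for high against middle at jointing, 426 and 452 for middle and high against low at big flare and 12 ordered genes, with 5, 9 and 2 lists for high against low, middle against low and high against middle. Without low jointing 2 and high jointing 1 they were 5036 for jointing to tasseling and 263 and 201 for high against low and high against middle at jointing, with 5 and 3 lists for high against low and middle against low.

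With each library left out in turn, the ranges were 1593 to 3975 for jointing to big flare. For middle against low they were 261 to 522, 363 to 647 and 350 to 680 at the 3 stages, for high against low 352 to 612, 469 to 777 and 491 to 1920, and for high against middle 169 to 328, 213 to 435 and 175 to 340. Ordered genes ranged from 14 to 24 and interaction genes from 7 to 20. Lists ranged from 0 to 6 for high against low, 1 to 9 for middle against low and 0 to 2 for high against middle. A left-out library leaves a group with 1 library, assumed to vary like the others.

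Replicate numbers do not pair the libraries: over 36 pairs of groups the correlation of same-numbered deviations ran from -0.43 to 0.29 (median -0.01, 8 over 0.1). With a replicate block the counts were 2293 for high against low, 1737, 1101, 2952, 10872 and 7722 for the other averaged contrasts, 12 for the interaction and 18 for ordered genes, all within 1.5 times the values without it. It ended the call of pectinesterase 21 (Zm00001d016907, 0.066) and brought the APG match Zm00001d019855 past the threshold (0.044).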

Other observations

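The following genes and terms were chosen after their values were seen. After the fall of benzoxazinless1 was seen, genes with benzoxazinoid names were looked up from jointing to tasseling: of 15 tested, itself included, 9 fell and 6 did not pass. They were no list fixed beforehand and were not tested as a set. Of 2 glucosidases, which release the compounds from their glucosides, Zm00001d023994 went from 28.6 to 131 FPKM (2.96, 0.104) and Zm00001d024891 from 17.8 to 1.1 (-1.66, 0.18). BX3 (Zm00001d048702) went from 1654 to 178 FPKM (log2 change -3.35, adjusted p = 8.82e-05), BX5 (Zm00001d048705) from 1572 to 165 (-3.35, 3.28e-05), BX4 (Zm00001d048703) from 1243 to 192 (-2.76, 4.3e-05) and benzoxazinone synthesis 2 (Zm00001d048710) from 359 to 20.3 (-4.25, 4.49e-06). BX13 (Zm00001d007718), whose best match is 1-aminocyclopropane-1-carboxylate oxidase, went from 30.5 to 0.11 FPKM (-3.50, 0.0355). Changes were smaller for bx8 (Zm00001d048707), by -0.52 (0.0383), and BX7 (Zm00001d049179), by -1.11 (0.0106), while bx6 (Zm00001d048634) gave -0.19 (0.703) and bx9 (Zm00001d031209) -0.17 (0.493).

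Among 578 Gene Ontology terms tested one-sided with a hypergeometric test against 18219 tested genes with a term, vesicle and protein transport stood out in the rise from big flare to tasseling: 107 of 212 protein transport genes rose (52 expected, adjusted p = 1.39e-13) and 53 of 87 genes of vesicle-mediated transport (21.3 expected, 1.64e-10). Of 31 microtubule motor genes 23 rose (7.6 expected, 3.97e-07). From jointing to tasseling, 14 of 16 genes of the V-type ATPase complex rose (3.4 expected, 1.44e-06). From jointing to big flare, 34 of 177 glycosyl hydrolase genes fell (9.2 expected, 1.77e-08) and 56 of 339 transcription factor genes rose (26.6 expected, 4.83e-05). These tests treat genes as independent, so their p-values are too small where genes move together. The high hybrid showed 5 of 17 phosphofructokinase genes higher than in the low hybrid (0.6 expected, adjusted p = 0.0475).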
